A study of Homo sapiens with 6 samples.

How the data were processed

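The data are one list of USP39 binding sites on RNA from HEK293T cells, an established human embryonic kidney line. USP39 is a protein of the U4/U6.U5 tri-snRNP, the particle that joins the spliceosome before splicing is activated. The assay was iCLIP2. Per the labels' protocols, cells were irradiated with 254 nm UV light, lysed and treated with RNase I, and USP39 was immunoprecipitated with an anti-USP39 antibody. After gel electrophoresis and transfer, a low and a high membrane region were taken, both at sizes over that of USP39 itself, which gave 2 groups of 3 libraries each, 6 in all. A first PCR of 6 cycles preceded size selection. The design text also names a control without UV light, which was not analysed here.

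Per the submitters' processing notes, the tools were FastQC 0.11.9, STAR 2.7.3a, SAMtools 1.10, bedtools 2.29.2 and UMI-tools 1.1.2, with the build GRCh38.p12; the notes used here give them without role or order. The merged list is filed under the low membrane region, replicate 1. The site caller, its filters and the libraries that went into the merged list are not given in the sources used here. The file is a BED list, and the score that the authors deposited for each site is 0 throughout, so it carries no height or rank. The deposited list has no values per library. Its read depth is unknown, no replicate error can be given for any site, and the low and high membrane regions could not be compared. No interval or p-value below measures the spread between libraries. Intervals from resampling genes and sign-flip tests measure the spread between genes in 1 merged list. The others rest on random lists, permutations or counting error within that list.

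Coordinates are those of the site list (GRCh38), written with the first base counted as 1. Gene names and neighbourhood came from a RefSeq gene table of assembly GRCh38.p14, used for 59716 genes with a position. The table gives neither strand nor exons, and no genome sequence was used. A site was given to a gene by its central base. Where genes of several classes held it, the order was snRNA, snoRNA, other small noncoding RNA, protein coding, lncRNA, pseudogene and other. Within a class, read-through loci and then symbols starting with LOC gave way to other genes. If several genes remained, the gene whose own sites (at least 3) lay mostly on the site's strand was taken, and otherwise the site counted for its class and for no gene, as happened to 425 sites. As a check of the coordinates, 98.0% of sites lay in a gene as deposited, against 64.8% after a shift of all sites by 1 Mb.

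The tests fixed before the data were examined included positions at 5' and 3' splice sites, transcript regions, U12-type introns, 5-mers and the site score. None of these was run, because they need exons, sequence or a varying score. The gene list test was run with random lists matched on 10 bins of gene length only, since intron numbers were not in the table; its 14 lists of protein-coding genes were compared with 10000 random lists each (two-sided permutation p, Benjamini-Hochberg adjusted over the 14 lists). For 6 lists of noncoding and mitochondrial genes only counts are given. All 667 list symbols were matched. Class shares have 95% intervals from 1000 draws of genes with replacement.

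The following were chosen after seeing the data. Positions along genes were measured in nuclear protein-coding genes with at least 3 sites, oriented by the strand with most of the gene's sites. Observed numbers were set against uniform placement within each gene, with 1000 bootstrap draws of genes and a two-sided sign-flip permutation test over genes (100000 resamples). The share of sites with a neighbour in the same gene within 50 nt was set against 200 uniform placements. The snoRNA genes were compared with 200 nt on each side, leaving out flank sites that lay in another small RNA gene. The length of such genes was not taken out of the flanks, which lowers the flank density. Positions in small RNA genes are counted from the 5' end by the strand of the site, and 6 RNA families were tested for an uneven split between their 5' and 3' parts. Shares of genes have 95% Wilson intervals, which cover counting error only.

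Named genes follow a rule fixed in advance: the 10 protein-coding and 5 noncoding genes with the most sites, each snRNA gene of the lists with a site, USP39, and 2 to 4 members of each list with the most sites. The parts of that rule on site scores and bound splice sites could not be applied. Other genes named below were chosen after their values were seen. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. Of 3000 simulated sites in genes free of overlap, 100% were given their own gene. For the gene lists, over 20037 genes, 4.0% of the unplanted lists and 100% of the planted lists had p under 0.05. For the position test, over 2362 genes, uniform placement gave a mean ratio of 1.01 and a planted ratio of 2.8 came back as 2.79. For the neighbour test on the same genes, uniform placement gave a ratio of 0.973. For the snoRNA flanks, over 1199 genes, planted ratios of 1 and 5 came back as 1.01 and 4.80. For the length classes, over 2166 genes, a gradient of fixed share gave permutation p = 0.304 and sites planted in the last 2000 nt gave p = 0.002. Alternatives were joining of sites within 10 or 50 nt, other rules for the class of a site, and other sets of genes.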

Results

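USP39-bound RNA was mapped by iCLIP2, which marks the places where UV light had joined a protein to RNA, in 6 HEK293T libraries from low and high membrane regions with 3 replicates each. One merged list of binding sites was analysed; it is filed under the low membrane region, replicate 1, and the sources used here do not say which of the 6 libraries were merged. It held 34781 binding sites, each 5 nt wide. The plus strand carried 17303 sites and the minus strand 17478. In the list, 5077 genes had at least 1 site counted for them, and 4289 of these were protein coding. The read depth behind a site is unknown, and the values have no replicate error because the list is merged. The question addressed here is in which RNAs USP39 sites lie. Positions at splice sites, the comparison that the series title was taken to imply, could not be tested. The low and high membrane regions were not compared, since no value belongs to one library.

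Most USP39 sites lay in protein-coding genes, with 31333 sites or 90.1% of the list (95% interval from resampling genes, 87.5% to 92.2%). The lncRNA genes held 1360 sites (3.91%, interval 1.78% to 6.70%), and 158 lncRNA genes had a site. The snoRNA genes held 653 sites (1.88%, interval 1.61% to 2.16%) in 247 genes, and the snRNA genes held 61 sites (0.175%, interval 0.106% to 0.251%) in 27 genes. Other small noncoding RNA genes, among them tRNA and vault RNA genes, held 433 sites (1.24%, interval 1.04% to 1.44%). Per kb of annotated gene, the order differed, with 4.90 sites per kb in snoRNA genes, 3.13 in snRNA genes and 0.0242 in protein-coding genes, whose spans include introns. With protein-coding genes placed before all other classes, the snoRNA share was 0.377% and the protein-coding share 92.0%, since most of the snoRNA sites also lay within the span of a protein-coding gene. With sites within 50 nt joined, an alternative chosen after seeing the data, the snoRNA share was 0.960%, with 1.97 joined sites per kb of snoRNA gene, and the snRNA share was 0.1095%.

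Among protein-coding genes, IRS4, a signalling adaptor of the insulin receptor substrate family on chromosome X, had the most sites, 180, between positions 108719983 and 108736331. DDX17, an RNA helicase gene on chromosome 22, had 163 sites between 38483470 and 38506309. HELLS, which encodes a chromatin remodeller, had 157 sites on chromosome 10 between 94545805 and 94613382. PRKDC, the catalytic subunit of DNA-dependent protein kinase, had 150 sites on chromosome 8 between 47773196 and 47957411. HNRNPC and OGT followed with 108 sites each, HNRNPH1 and SLIT2 with 106 each, PRRC2B with 104 and SRRM2 with 94. The densest 1000 nt of these genes held from 4.67% of the sites in PRKDC to 17.9% in HNRNPH1. The median protein-coding gene with a site had 3 sites, 1277 genes had 1 site, and the 43 genes with the most sites (1% of those with a site) held 11.9% of the sites in protein-coding genes. With sites within 50 nt joined, an alternative chosen after seeing the data, HELLS came first of these 10 genes with 116 sites, before PRKDC with 108 and IRS4 with 107, while DDX17 had 97, OGT 68 and HNRNPH1 58.

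The sites followed 1 strand of each gene. Of 1665 protein-coding genes with 5 or more sites, 1645 had every site on the same strand, and 99.9% of the sites in the 1665 genes lay on the gene's main strand. Where genes overlap, a site's strand could decide the gene it was counted for, so the count was repeated, after seeing the data, in genes that overlap no other: 703 of 705 had every site on 1 strand. The gene table gives no strand, so the main strand was not compared with the annotated one.

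The noncoding genes with the most sites were lncRNA genes. XIST, the RNA that coats the inactive X chromosome, had 357 sites on chromosome X between 73820732 and 73852712. NEAT1, the scaffold of nuclear paraspeckles, had 243 sites on chromosome 11 between 65422922 and 65445456, and its neighbour MALAT1 had 91 between 65499041 and 65506013. JPX and FTX, both neighbours of XIST, had 73 and 42 sites. With sites within 50 nt joined, XIST had 194 sites and NEAT1 150, and JPX with 65 came before MALAT1 with 46, with FTX at 36. In the fixed list of lncRNA genes, 6 of 9 had a site, NORAD with 22 and TUG1 with 16 among them. KCNQ1OT1 had 5 sites within its span that were not counted for it. The gene table classes TUG1 as protein coding, so its sites were counted in that class. Among the snoRNA host genes, 9 of 13 had a site that was counted for the host itself, led by GAS5 with 31 and by SNHG1 and SNHG16 with 27 each. The other 4 hosts had sites within their spans that were counted for other genes, 51 of them within SNHG3, 15 within SNHG7, 8 within SNHG6 and 5 within EPB41L4A-AS1.

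USP39 sites were found in the RNA genes of both spliceosomes. All 4 minor spliceosome snRNA genes had sites, with 5 each in RNU11 and RNU12, 4 in RNU6ATAC and 2 in RNU4ATAC. Of the 36 listed genes of the major snRNAs, 19 had a site, with 36 sites in all. Each of the 5 U5 genes (RNU5A-1, RNU5B-1, RNU5D-1, RNU5E-1 and RNU5F-1) had a site centred on position 40 from its 5' end, and those genes held 9 sites in all. The shared site lay at 65296088 to 65296092 on chromosome 15 in RNU5A-1 and at 65304714 to 65304718 on chromosome 15 in RNU5B-1. On chromosome 1 it lay at 44731129 to 44731133 in RNU5D-1, at 11908189 to 11908193 in RNU5E-1 and at 44721861 to 44721865 in RNU5F-1. Neither of the U4 genes, RNU4-1 and RNU4-2, had a site, although U4 is a part of the tri-snRNP. Of the 5 U6 genes, RNU6-9 had 2 sites and RNU6-1 had 1. The U1 genes held 21 sites in 11 of 21 genes, all but RNU1-4 being U1 variants (RNVU1), with 4 sites in RNVU1-15 and 3 in RNVU1-31. In 6 of these 11 genes a site was centred on position 28 or 29. The U2 genes, counted with those under LOC symbols, held 8 sites in 4 of 11 genes. RNU2-2 had 3 sites on chromosome 11, at positions 75, 92 and 99 from its 5' end, and LOC124904145 also had a site at position 99. RNU7-1, whose RNA acts in histone mRNA processing rather than in splicing, had 4 sites. These genes belong to families of near-identical copies and pseudogenes, so the number of sites in any one U1, U2, U5 or U6 copy is uncertain.

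**Figure D1:**
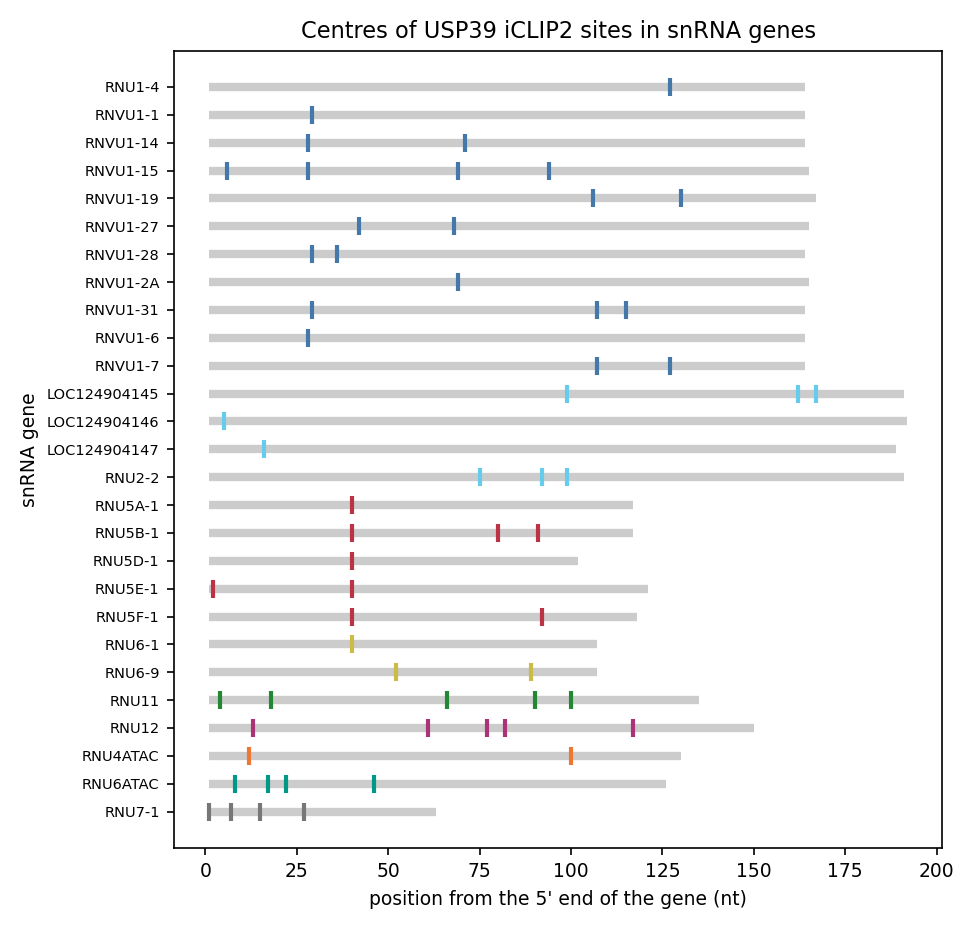
Each grey bar is an snRNA gene with at least 1 site, drawn to its length in nt from the 5' end, and each tick is the centre of a binding site, coloured by snRNA family. The 5 U5 genes share a site at position 40, and 6 of the 11 U1 genes have a site at position 28 or 29.

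Small nucleolar RNA genes carried more sites than their surroundings. Over 1199 snoRNA genes the density was 4.90 sites per kb within the genes and 1.04 per kb in the 200 nt on each side. The ratio was 4.70 (interval 4.10 to 5.38, sign-flip permutation p = 1e-05, the smallest it can give). Flank sites in other small RNA genes were left out while the length of those genes stayed in, which raises the ratio by an unknown amount. RNA abundance was not measured, so the ratio is not corrected for how much RNA the genes and their flanks give. It therefore does not show a preference of USP39 for snoRNAs. C/D box genes (SNORD), whose RNAs guide ribose methylation, held 395 sites in 148 of 357 genes (41.5%, Wilson interval 36.5% to 46.6%). Without the SNORD113 to SNORD116 genes, left out after their values were seen, the share was 61.9% of 239 genes (Wilson interval 55.6% to 67.8%). H/ACA box genes (SNORA), which guide pseudouridylation, held 256 sites in 97 of 182 genes (53.3%, Wilson interval 46.1% to 60.4%). Small Cajal body RNA genes (SCARNA) had a site in 25 of 29 (86.2%, Wilson interval 69.4% to 94.5%), with 7 sites in SCARNA10. In C/D box genes 84.8% of the sites lay in the 5' part of the RNA, up to its midpoint (permutation p = 1e-05, adjusted p = 3e-05 over 6 families), and 176 of the 395 lay in the first 20 nt against 0 in the last 20 nt. In H/ACA box genes 54.7% of the sites lay in the 5' part (adjusted permutation p = 0.168), with 32 in the first 20 nt and 3 in the last 20 nt. An alternative chosen after seeing the data left out sites in the middle 20% of each gene. Its p-values were adjusted over C/D box, H/ACA box and nuclear tRNA genes only. The share in the 5' part was then 91.9% in C/D box genes (adjusted permutation p = 3e-05) and 59.3% in H/ACA box genes (adjusted permutation p = 0.0179). The SCARNA genes had 9 and 0 sites in these end parts, the snRNA genes 13 and 1, and the nuclear tRNA genes 33 and 41. Whether sites in the last 20 nt of such short RNAs could be detected was not tested. An even split may therefore be the wrong baseline, and a preference of USP39 for the 5' part is not shown.

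The list also held sites in other short RNAs. The control without UV light was not analysed and RNA abundance was not measured, so these sites are not shown to exceed background. The same limit holds for every other site in the list, those in snRNA, snoRNA, lncRNA and protein-coding genes included. Nuclear tRNA genes held 250 sites in 179 of 443 genes (40.4%, Wilson interval 35.9% to 45.0%), and 66.4% of those sites lay in the 5' part (adjusted permutation p = 3e-05). Of the 250 tRNA sites, 138 lay in the middle 20% of the gene, around the midpoint. Of the other 112, 44.6% lay in the 5' part (permutation p = 0.339, adjusted together with the C/D and H/ACA box genes only). TERC, the RNA template of telomerase, had 9 sites. RMRP and RPPH1, the RNA subunits of RNase MRP and RNase P, had 7 and 5 sites. The vault RNA genes VTRNA1-1 and VTRNA1-2 had 5 sites each. RN7SL1 and RN7SL2, the RNA of the signal recognition particle, had 3 sites each, and RNY5 and RNY1 had 3 and 2. In the list of other noncoding RNA genes 7 of 10 had a site, and the 3 without were RN7SK, RNY3 and RNY4.

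Genes for splicing factors were among those with USP39 sites more often than random genes of matched length. The random genes were drawn without regard to expression in HEK293T cells. A higher share can therefore reflect expression alone, and a preference of USP39 for these genes is not shown. In the tri-snRNP and LSm list, 17 of 22 genes had a site against 5.32 in random lists (adjusted permutation p = 0.000233, raw p = 0.0002, the smallest it can give). PRPF8, the central protein of the spliceosome, had 81 sites, SNRNP200 had 21, LSM4 had 10 and EFTUD2 had 6. USP39 itself had 5 sites on chromosome 2 between 85621571 and 85649012. All 23 genes of the U1, U2 and Sm list had a site (random mean 5.10), with 50 in SNRNP70, 41 in SF3B3 and 24 in SF3B1. The SR protein list had 12 of 14 genes with a site (random mean 3.11), among them SRSF11 with 88 sites, SRSF1 with 57 and TRA2A with 39. Of the hnRNP list 23 of 24 genes had a site (random mean 5.46), with 91 sites in HNRNPU and 82 in HNRNPA2B1. The adjusted p was 0.000233 for these lists as well.

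The same was found for lists outside splicing. Ribosomal protein genes had a site in 77 of 85 (random mean 15.6), with 46 sites in RPL3, 42 in RPL5 and 37 in RPL4. RPL15 and RPL35A had 0 counted for them, although 27 and 14 sites lay within their spans. Replication-dependent histone genes had a site in 37 of 68 (random mean 7.53), with 12 in H2BC12, 10 in H2BC21 and 9 each in H2BC5 and H4C4. H2AC7 and H3C4 had 0 counted for them, although 6 sites lay within the span of each. Of these 68 genes, 60 span at most 1000 nt, and 32 of the 60 had a site; the sites of H2BC12 covered a longer stretch, from 27138400 to 27146858 on chromosome 6. Oxidative phosphorylation genes had a site in 64 of 82 (random mean 16.1), led by ATP5F1A with 27 and ATP5F1B with 26. Translation factor genes had a site in 46 of 70 (random mean 16.1), with 73 in EEF2 and 61 in EEF1D. The list took every gene whose symbol starts with EEF or EIF and a digit. It thus includes genes such as EEF2K and EEF1AKMT1 that are not themselves translation factors. Proteasome genes had a site in 27 of 32 (random mean 7.20), with 17 in PSMA4 and 11 each in PSMB1 and PSMB2. Genes of folding and stress in the endoplasmic reticulum had a site in 24 of 34 (random mean 7.53), with 63 in CANX and 29 each in HSP90B1, P4HB and PDIA6. Mitosis genes had a site in 14 of 17 (random mean 3.998), with 14 in TOP2A and 11 in CENPF. All 16 housekeeping genes had a site (random mean 3.27), with 54 in NPM1 and 52 in ENO1 after EEF2. The adjusted p was 0.000233 in each of these 8 lists.

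Ubiquitin-specific proteases, the family whose name USP39 carries, had a site in 19 of 51 genes (random mean 11.9, adjusted permutation p = 0.0358), with 66 sites in USP9X and 36 in USP22. With at least 3 sites required, the adjusted p of this list was 0.0915. Of 20 genes restricted to other tissues, such as ALB, APOA1, INS and HBB, 0 had a site (random mean 3.69, adjusted permutation p = 0.0355), and with at least 3 sites required the adjusted p was 0.201. No RNA abundance was measured, so the counts are not corrected for how strongly the genes are expressed in HEK293T cells. Among genes that had a site, the share with 5 or more sites was higher than in random lists for the SR, hnRNP, ribosomal protein, oxidative phosphorylation, translation and housekeeping lists, and did not pass the test for the other 7 lists with a site, the tri-snRNP list among them with 7 of 17 genes against 7.05 in random lists (adjusted permutation p = 1.0) and the U1, U2 and Sm list with 12 of 23 against 9.47 (adjusted permutation p = 0.506).

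**Figure D2:**
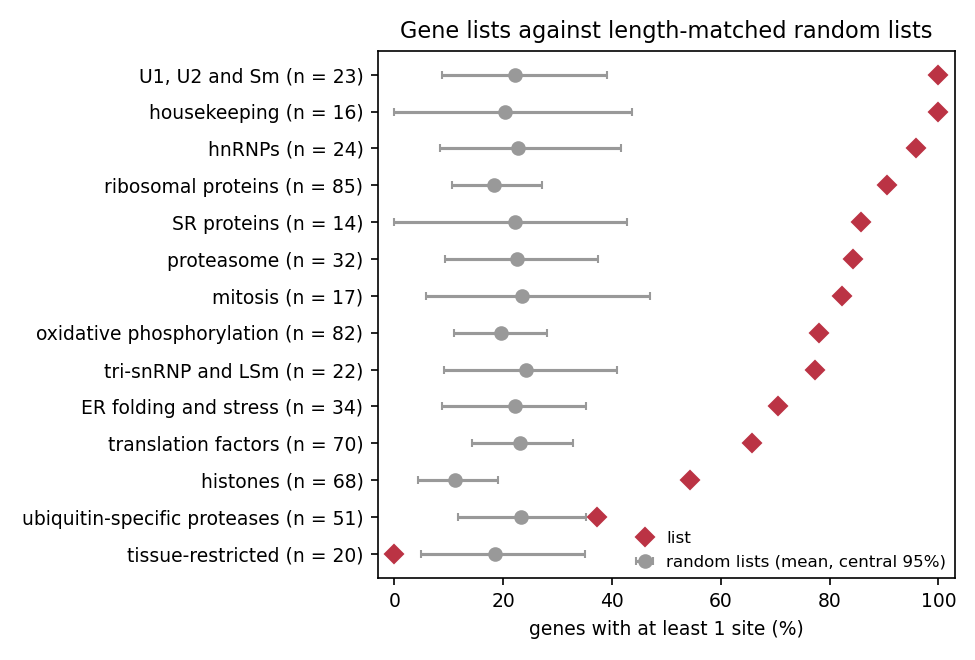
The horizontal axis gives the percent of genes with at least 1 site for 14 gene lists; diamonds are the lists, grey circles the mean of 10000 random lists matched on gene length, and bars their central 95%. Apart from the tissue-restricted list at 0%, the lists lie above the upper end of the bars.

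Along protein-coding genes, sites were most frequent at the 3' end. Of 28345 sites in 2362 genes with 3 or more sites, 6901 (24.3%) lay in the last 10% of the gene, 2.43 times the number under uniform placement (interval 2.32 to 2.56; sign-flip permutation p = 1e-05, the smallest it can give). The first 10% held 2907 sites (10.3%), a ratio of 1.03 (interval 0.954 to 1.104, sign-flip permutation p = 0.485). Of 10 equal bins, the ratio was lowest in bin 3, at 0.654. Single genes differed, with 50.8% of the sites of CANX, 66.7% of those of USP22 and 55.2% of those of PDIA6 in the last 10%, against 5.66% in SLIT2 and 2.44% in HNRNPA2B1. Exons were not known here, so these positions do not separate 3' untranslated regions from introns.

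**Figure D3:**
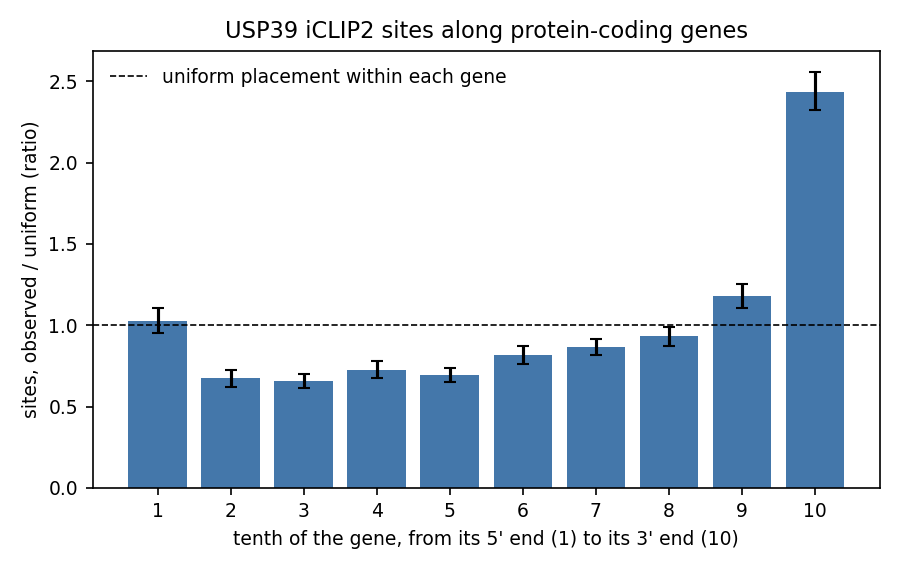
Bars show the ratio of observed sites to uniform placement in 10 equal bins of 2362 protein-coding genes, from the 5' end (1) to the 3' end (10); error bars are 95% intervals from resampling genes and the dashed line is a ratio of 1. Bin 10 stands at 2.43 and bin 1 at 1.03.

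Sites also lay close together. In these genes 35.2% of sites had a neighbour in the same gene within 50 nt, against a mean of 13.2% and a maximum of 14.0% in 200 uniform placements. Uniform placement covered the whole gene, so crowding at the 3' end, or in exons, which were not known, would also raise this share. Abutting sites counted as neighbours too. The smallest distance between the starts of neighbouring sites on a strand was 5 nt and the median 355 nt. Across protein-coding genes with a site, the number of sites and the length of the gene were weakly and inversely related (Spearman's rho across genes, which are not independent replicates, -0.1103).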

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

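The tests on U5 and on gene length classes were chosen after their results were seen; the other tests on gene ends and those on small RNAs were set out before their results were seen, but after the patterns were.

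No gene of the table held 689 sites (1.98%), a signal outside the gene comparisons. These sites were counted in fixed bins of 10000 nt. The bin with the most had 23, all on the minus strand of chromosome 1 between 244845200 and 244849871. They adjoined the sites of HNRNPU, which start at 244850444 on the same strand. The next bin had 21 sites, all on the plus strand of chromosome 21 between 8990062 and 8994705. The bin before it on chromosome 21 held 11 more on that strand, between 8988740 and 8989934. A bin edge thus split this cluster, which as a whole held more sites than the bin on chromosome 1. The mitochondrial chromosome, also outside the comparisons, had 19 sites, all on the minus strand between positions 57 and 4368, with 12 of them within ND1 and 1 each within TRNI, TRNL1 and TRNQ. Of 37 mitochondrial genes, 4 had a site within their span. ND1, TRNI and TRNL1 are encoded on the plus strand, so the sites within them lay antisense to these genes. On chromosome 1 between 629913 and 634105, where the table lists copies of mitochondrial genes, there were 13 sites, 7 of them in MTATP6P1 and 4 in MTND2P28.

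Sites crowded in the last 10% of protein-coding genes (ratio 2.43), and a few genes with very many sites are argued against, as the ratio was 2.54 (interval 2.42 to 2.65) without the 1% of genes with the most sites. Runs of adjacent sites are argued against by a ratio of 2.39 (interval 2.28 to 2.51) with sites within 50 nt joined, and overlapping genes by a ratio of 2.35 (interval 2.17 to 2.52) in genes that overlap no other. In the last 2000 nt the ratio to uniform placement was 1.39 in the shortest of 3 length classes of genes and 5.52 in the longest, 3.97 times higher, over the 2166 genes longer than 4000 nt, while the percent of sites in that window fell from 31.2% to 14.1%. With gene lengths permuted among these genes, as for positions that depend on the share of the gene alone, that factor was 2.13 on average (central 95% 1.85 to 2.42; permutation p = 0.002, the smallest that 1000 permutations can give), so a 3' part of fixed length may underlie part of the pattern. The design holds no group that would test a biological explanation, and exon positions stay open.

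Many small RNA genes had no site, RN7SK, RNU4-1 and RNU4-2 among them. If reads that match several places had been dropped, families with many pseudogenes should have fewer sites per gene. Over 20 small RNA families Spearman's rho between sites per gene and pseudogenes was -0.663 (permutation p = 0.00169; -0.712 without the 2 families farthest from the median), and Pearson's r was -0.304 (permutation p = 0.184; -0.438 without those 2), so the relation holds in rank and loss of shared reads is a candidate explanation. For tRNA genes, 34.7% of 222 genes with identical copies had a site against 50.2% of 201 without. The ratio was 0.690 (interval 0.545 to 0.864, Fisher's exact test, two-sided p = 0.00157). This is neither as low as 0.5 nor as high as 0.8, the bounds set before, and leaves the part of identical copies open. Some copies shared positions: RN7SL1 and RN7SL2 both had sites at 232, 242 and 250, and TRA-AGC2-1 and TRA-AGC2-2 both at 36. Sites in copies were thus not always lost. These genes were chosen after their values were seen. No biological explanation was tested.

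All 5 U5 genes had a site at position 40. A possible explanation is reads shared between near-identical copies, which would put a site of one gene on all. The share of the other 4 sites at exactly the position of a site in another of the genes was 0, while 2 of the 4 lay within 1 nt of one, so the outcome turns on the tolerance and 4 sites are too few to decide it. Chance was not tested, since the family was singled out for its shared position, and 6 of 11 U1 genes also had a site at position 28 or 29. No biological explanation was tested.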

How the results depend on the processing

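Alternatives named below as joining within 50 nt, genes free of overlap, 5 or more sites, or sets of genes for positions were chosen after seeing the data. No paired analysis was possible because the list is merged and its columns carry no replicate number; for the same reason no replicate was left out. Of 81 alternatives fixed before the data were examined, 4 were run; 77 needed exons, sequence, gene strand, intron numbers or a score that varies, or values per library. Joining sites changed the total of 34781 by less than 1.5 times. Joining within 50 nt moved the shares to 92.0% protein coding, 3.33% lncRNA, 0.960% snoRNA, 0.1095% snRNA and 0.971% other small RNA. Protein-coding genes placed first gave 92.0% protein coding, 0.377% snoRNA and 0.848% other small RNA, by the construction of that order, and any overlap instead of the central base gave 2.22% snoRNA. The other shares of the classes named here moved by less than their binomial interval. Shares of pseudogenes, of the remaining class and of sites in no gene were not compared. At least 3 sites weakened the ubiquitin-specific protease list (ratio 1.76, adjusted permutation p = 0.0915) and the tissue-restricted list (ratio 0, adjusted p = 0.201), as did joining for the first (1.52, adjusted p = 0.0630) and genes free of overlap for the second (0, adjusted p = 0.182, with 13 genes left); the other 12 lists stayed past the threshold under these settings. Among genes with a site, 5 or more sites gave ratios no longer past the threshold for U1, U2 and Sm (1.27), histones (1.23), endoplasmic reticulum (1.36), proteasome (1.11) and ubiquitin-specific proteases (1.47), and ratios below 1 for tri-snRNP (0.993) and mitosis (0.708), neither past the threshold; 6 lists stayed past it. The cause was not tested. The ratio of the last 10% of genes ranged from 2.30 with at least 10 sites per gene to 2.54. The ratio of the first 10%, never past the threshold, turned to 0.966 with at least 10 sites. The ratio of close neighbours to uniform placement was 2.67, and between 2.14 within 100 nt and 3.61 within 20 nt. The snoRNA ratio of 4.70 was 5.81 with flanks of 500 nt and 3.60 with joined sites. Without sites in the middle 20% of the gene, the share of sites in the 5' part turned from 66.4% to 44.6% in tRNA genes, no longer past the threshold, as the sites around the midpoint carried it, and in H/ACA box genes it passed the threshold at 59.3%. Depth is unknown, so a gene without a site is not shown to be unbound.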

Other observations

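Among the autosomes, sites per protein-coding gene were highest on chromosome 22, at 2.82, and on chromosome 1, at 2.20. They were lowest on chromosome 18, at 0.674, and on chromosome 4, at 0.919. Chromosome X, which carries IRS4, OGT and USP9X, had 2.00 sites per protein-coding gene, apart from the 357 sites in XIST.

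SNORD92, with 7 sites, had the most of the C/D box genes. None of the 118 listed genes of the SNORD113 to SNORD116 clusters had a site, whereas 148 of the other 239 C/D box genes did (61.9%, Wilson interval 55.6% to 67.8%). These genes were chosen after their values were seen.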
